A study of Mus musculus with 1104 samples.

How the data were processed

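For each organ 6 male C57BL/6 mice per time point gave poly(A) RNA, from which stranded libraries were made, per the labels' protocols; the diet began at 8 weeks of age and held 60 kcal% fat. The deposited values are whole-number read counts per gene symbol, and the columns of the 1104 libraries name organ, time point and replicate. Per the submitters' processing notes, FastQC 0.11.7, Trimmomatic 0.38, HISAT2 2.1.0, SAMtools 1.9 and featureCounts 1.6.3 were used with build GRCm38 (mm10); the annotation and the strand setting of the counting are not given in the sources used here, so genes that overlap on opposite strands may share reads. Genes of near-identical families share or lose reads in such counting. Of 20646 symbols 20319 matched the GENCODE M21 reference, which gave coordinates, GC content and transcript length. Libraries were checked for repeats: counts differed beyond sampling noise in every pair within a group, which speaks against a library deposited under 2 names but does not show that the mice were separate, with a lowest chi-square per degree of freedom of 2.13 in hypothalamus and 4.27 in epididymal fat. Totals per library ran from 7670532 to 27036098; at the median of 13464321 a gene at 1 CPM has about 13 counts, so that low genes are limited by counting error, and intervals and floors cover counting error alone.

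Each organ was fitted on its own, with all of its libraries (84, or 96 in epididymal fat) and 1 coefficient per time point, by edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, which left 12391 (pancreas) to 15225 (epididymal fat); libraries were scaled by TMM, dispersions estimated with the design, and each time point was compared with 0 days by glmQLFit and glmQLFTest, two-sided. The p-values of a comparison were adjusted by Benjamini and Hochberg, and 0.05 was the threshold. The standard error is the log2 fold change over the square root of F. The interactions used 1 fit of both organs with organ by time coefficients. In all, 60 gene lists (pathways, cell types, and markers of other tissues) were compared with all other genes by camera of limma 3.58.1 with an estimated correlation, and list p-values were adjusted over the lists of a comparison. Levels are CPM with TMM factors. The genes named were those with the 5 highest and 5 lowest log2 fold changes at 12 weeks with a mean of at least 5 CPM (4 and 4 at 1 week, and also at 20 weeks), the 4 members of each list with the smallest p, the 5 with the smallest p per direction in the interactions, the 5 with the smallest p for spread at the time with most calls, and the 10 called in most organs. The comparisons, tests, lists, this rule and most alternatives were fixed before the data were examined; the offsets, the counts with 1 library fewer and the square roots were added later.

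Slopes were fitted to log2 CPM (prior count 2) against log2 days from 1 day to 10 weeks, and the share of 12-week calls with the same sign was compared with 10000 permutations of the time points. Spread was the absolute deviation of log2 CPM from the time point mean, compared by limma between 1 time point and the others, one-sided, and repeated on 40 permutations of libraries over time points. Spread over all genes and the share of the first principal component were compared by 1e+05 permutations. Alternatives were RLE size factors, no filter on low counts, DESeq2 1.42.0, voom with quality weights, a fit of the 2 groups alone, the replicate number as a block, offsets from splines (5 degrees of freedom) on GC content and transcript length, and 1 library fewer per time point, the one with the lowest median correlation with the other 5; for lists, camera with a preset correlation of 0.01 and fry; for spread, squared deviations and square roots of the deviations. For each comparison by edgeR 30 splits of the libraries, the real one included, were fitted. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 drew the plots.

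The fits were tested on simulated data, drawn from the means, dispersions and library sizes of the real libraries with 200 changed genes. For 12 weeks edgeR recovered 74.6% of 1.5-fold, 92.5% of 2-fold and 100% of 4-fold changes in liver, 35.8%, 85.1% and 95.5% in epididymal fat, and 11.9%, 53.7% and 92.4% in soleus; for the interaction of the fat depots it recovered 23.9%, 61.2% and 87.9%. False calls made up 2.73% to 5.41% of the calls. The test of spread was liberal: in simulated liver data with 3-fold deviations at 5 weeks it recovered 160 of 200 genes, but 81 of its 241 calls were false, and the other 13 time points had up to 30 false calls each. With square roots of the deviations 127 genes were recovered, 21 of 148 calls were false, and the other time points had at most 3. No library was left out of the fits that the text leads with, and results of a few genes are not reported here.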

Results

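Messenger RNA was measured by RNA-seq in 13 organs of male C57BL/6 mice fed a high-fat diet, in which most of the energy comes from fat, for up to 12 weeks. The organs were interscapular brown fat, epididymal and inguinal white fat, liver, pancreas, small intestine, soleus and gastrocnemius muscle, hippocampus, neocortex, hypothalamus, pituitary gland and olfactory bulb. Each organ had 14 time points (0, 1 and 3 days, 1 week, 10 days, and 2, 3, 4, 5, 6, 7, 8, 10 and 12 weeks), epididymal fat also 16 and 20 weeks, with 6 mice at each, which gave 184 groups and 1104 libraries. The series asks how expression, and its variation between mice, moves in many organs as metabolic syndrome develops. The deposited table held raw counts of 20646 genes, and the total per library ran from 7670532 to 27036098 with a median of 13464321. Pancreas had the lowest median, 9331883.5, and the pituitary 15261199.5. Every later time point was set against 0 days, since mice kept off the diet were not analysed here, so that diet, age and day of dissection change together. Changes are log2 fold changes ± standard error with n = 6 mice per time point, and levels are in CPM, counts scaled to library size (mean ± SD, n = 6). Coordinates are on GRCm38, and genes called at an adjusted p under 0.05 are said to have risen or fallen. Genes of near-identical families (the major urinary proteins, Cyp2 and Cyp4a enzymes, Hspa1a with Hspa1b, globins, serpins, trypsins, kallikreins and ribosomal proteins) share reads, and their single values are uncertain.

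In liver, genes of lipid storage rose over 12 weeks. Cidec, which enlarges lipid droplets (chromosome 6, 113424634 to 113435760, minus strand), rose from 5.23 ± 0.542 to 106 ± 32.3 CPM, a log2 fold change of 4.33 ± 0.35. The apolipoprotein gene Apoa4 rose from 123 ± 35.5 to 3610 ± 1270 CPM (4.88 ± 0.36), and all 6 mice at 12 weeks lay above all 6 at 0 days for both. Osbpl3, an oxysterol-binding protein, rose by 5.05 ± 0.38 and Cd36, the fatty acid transporter, by 2.8 ± 0.19. Of 17 lipid droplet genes and PPARG targets, 16 rose, 16 adjusted over the list alone, with a median of 2.55 (adjusted p = 0.0266 with an estimated correlation). Sqle, an enzyme of sterol synthesis, rose from 6.4 ± 2.27 to 61.6 ± 16.3 CPM (3.28 ± 0.3). Of 24 cholesterol synthesis genes, 23 rose, 23 adjusted over the list alone, with a median of 1.43 (adjusted p = 0.126 with an estimated correlation). Fatty acid synthesis moved the same way, with Elovl5 at 2.59 ± 0.24 and Fasn at 1.7 ± 0.22. Of 18 lipogenic genes, 16 rose and 1 fell, 17 and 1 adjusted over the list alone, with a median of 0.94 (adjusted p = 0.157 with an estimated correlation). Of 30 PPAR targets and genes of fatty acid oxidation, 21 rose and 1 fell, 23 and 1 adjusted over the list alone, with a median of 0.52 (adjusted p = 0.157 with an estimated correlation), led by Vnn1 (2.96 ± 0.3) and Acadm (0.69 ± 0.08).

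Genes with higher expression in male than in female liver fell. Hsd3b5, a steroid dehydrogenase of male liver (chromosome 3, 98618634 to 98630252, minus strand), went from 204 ± 98.4 to 4.05 ± 8.03 CPM (-5.64 ± 0.57). Replicate 6 at 12 weeks kept 20.4 CPM, and the other 5 lay between 0.201 and 2.11. Serpina1e (-4.47 ± 0.38) and Cyp4a12b (-3.92 ± 0.32) of the male-biased list fell as well. Cyp2c69 (-7.87 ± 0.69) and Cyp2c40 (-7.23 ± 0.63) had larger falls. They are on neither the male-biased nor the female-biased list and are no evidence for this pattern. Of 16 male-biased genes, 13 fell, 14 adjusted over the list alone, with a median of -1.82 (adjusted p = 0.126 with an estimated correlation). Of 5 female-biased genes, 3 rose and 2 fell, 3 and 2 adjusted over the list alone, with a median of 3.04 (adjusted p = 0.628 with an estimated correlation), led by Cyp2b9 (5.76 ± 0.63). Collagen genes rose, Col1a1 by 2.38 ± 0.3 and Col3a1 by 1.69 ± 0.25, as did the complement factor D gene Cfd (7.21 ± 0.92). Of the matrix list 19 of 24 members rose, 20 adjusted over the list alone, with a median of 0.77 (adjusted p = 0.17 with an estimated correlation). Division genes also rose (Mki67 1.77 ± 0.29, Mcm2 1.53 ± 0.21). Of 19 cell cycle genes, 14 rose, 15 adjusted over the list alone, with a median of 1.17 (adjusted p = 0.126 with an estimated correlation). Markers of lipid-associated macrophages went mostly up, Gpnmb by 4.5 ± 0.57. Of 18 markers, 12 rose and 3 fell, 13 and 3 adjusted over the list alone, with a median of 0.95 (adjusted p = 0.126 with an estimated correlation). At 12 weeks 2591 genes were higher and 2696 lower of 12592 tested, 698 of them at least 2-fold, and the genes named here had adjusted p of at most 5.7e-07. After 1 week 654 genes were higher and 699 lower. With offsets for GC content and transcript length the calls were 2014 higher and 3226 lower at 12 weeks, and 554 higher and 894 lower at 1 week. Of early calls the urinary protein gene Mup18 (2.92 ± 0.53) was higher and the drug-metabolising genes Cyp3a11 (-2.89 ± 0.22) and Gsta2 (-2.68 ± 0.33) lower.

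Epididymal white fat had the most calls of any organ at 12 weeks, 4726 higher and 4464 lower of 15225 tested, 4119 of them at least 2-fold. Itgax, which encodes CD11c of tissue macrophages (chromosome 7, 128129547 to 128150657, plus strand), rose from 8.94 ± 2.59 to 364 ± 112 CPM (5.35 ± 0.34), and the macrophage gene Adgre1 by 3.4 ± 0.23. Of 19 macrophage genes, 18 rose, 18 adjusted over the list alone, with a median of 2.22 (adjusted p = 0.159 with an estimated correlation). Markers of macrophages loaded with lipid rose, such as the lysosomal genes Lipa (3.19 ± 0.22) and Ctsk (3.64 ± 0.26). Of 19 such genes, 17 rose and 1 fell, 17 and 1 adjusted over the list alone, with a median of 3.07 (adjusted p = 0.159 with an estimated correlation). The chemokine Ccl2 rose by 3.92 ± 0.39 and the interleukin antagonist Il1rn by 5.34 ± 0.48. Of 17 cytokine and chemokine genes, 12 rose and 2 fell, 12 and 2 adjusted over the list alone, with a median of 1.61 (adjusted p = 0.37 with an estimated correlation). All measured division genes were among the calls, Mki67 at 3.46 ± 0.32 and Top2a at 3.13 ± 0.31. Of 21 cell cycle genes, 21 rose, 21 adjusted over the list alone, with a median of 2.2 (adjusted p = 0.269 with an estimated correlation). Matrix genes rose, Lum by 2.06 ± 0.18 and Timp1 by 4.14 ± 0.46. Of 26 such genes, 23 rose, 24 adjusted over the list alone, with a median of 1.34 (adjusted p = 0.393 with an estimated correlation).

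Leptin, the adipocyte hormone that reports fat stores (Lep, chromosome 6, 29060220 to 29073877, plus strand), rose in the same libraries from 374 ± 127 to 3320 ± 888 CPM (3.15 ± 0.3), whereas most other adipocyte genes fell. Adrb3, the adrenergic receptor of lipolysis, went from 1080 ± 293 to 69.6 ± 30.6 CPM (-3.96 ± 0.39), and the insulin-responsive glucose transporter Slc2a4 (-2.23 ± 0.21) and Cfd, adipsin, (-5.97 ± 0.55) fell too. In sum 2 of 16 adipocyte genes rose and 13 fell, 2 and 13 adjusted over the list alone, with a median of -1.16 (adjusted p = 0.296 with an estimated correlation). Respiratory chain genes such as Sdha (-0.66 ± 0.09) fell. Of 32 oxidative phosphorylation genes, 20 fell, 20 adjusted over the list alone, with a median of -0.57 (adjusted p = 0.747 with an estimated correlation). Sterol synthesis rose, with Hmgcs1 at 2.25 ± 0.18 and Dhcr7 at 2.79 ± 0.24. Of 24 such genes, 18 rose, 18 adjusted over the list alone, with a median of 1.24 (adjusted p = 0.269 with an estimated correlation). The choline transporter gene Slc5a7 had 0 counts in the 6 mice at 0 days and 15041 at 12 weeks, at least 6270-fold higher against a floor of 3 counts over the group, and by the same floor the lipase gene Lipf was at least 667-fold higher. Adjusted p was at most 1.7e-09 for the genes given with a fold change. After 1 week 3056 genes were higher and 2482 lower, a balance that depended on the scaling (2591 higher and 2911 lower with RLE size factors, 3869 higher and 2007 lower with offsets for GC content and length). Of 26 matrix genes, 20 rose and 1 fell, 20 and 1 adjusted over the list alone, with a median of 0.96 (adjusted p = 0.846 with an estimated correlation). Of 21 cell cycle genes, 13 rose, 13 adjusted over the list alone, with a median of 1.04 (adjusted p = 0.846 with an estimated correlation). Foxj1, a gene of ciliated epithelium, was lower by then (-3.51 ± 0.65).

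At 20 weeks epididymal fat was also set against 0 days, and 4722 genes were higher and 4535 lower (4344 and 4957 with RLE size factors), 4036 at least 2-fold. The B cell gene Cd22 rose by 4.92 ± 0.45, Jchain of antibody-secreting cells by 4.69 ± 0.61 and Cd8a of cytotoxic T cells by 4.48 ± 0.56. Of 11 B cell genes, 11 rose, 11 adjusted over the list alone, with a median of 3.69 (adjusted p = 0.202 with an estimated correlation). Of 14 T cell genes, 12 rose, 12 adjusted over the list alone, with a median of 2.14 (adjusted p = 0.202 with an estimated correlation). Macrophage genes were high at this age too (Itgax 5.17 ± 0.34, Gpnmb 6.23 ± 0.5). Of 19 lipid-associated macrophage genes, 17 rose and 1 fell, 17 and 1 adjusted over the list alone, with a median of 2.63 (adjusted p = 0.154 with an estimated correlation). On the other side 2 of 16 adipocyte genes rose and 14 fell, 2 and 14 adjusted over the list alone, with a median of -1.19 (adjusted p = 0.202 with an estimated correlation), including the lipase gene Lipe (-1.5 ± 0.15) and Adrb3 (-4.43 ± 0.4), with adjusted p of at most 3.1e-10 for the named genes.

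Inguinal white fat showed a rise of lipid-handling macrophage genes and a loss of lymphocyte genes at 12 weeks. Plin2, which coats lipid droplets, rose by 2.18 ± 0.21, the lysosomal protease Ctsl by 1.67 ± 0.17 and the proton pump subunit Atp6v0d2 by 3.96 ± 0.49. Of 19 lipid-associated macrophage genes, 16 rose, 16 adjusted over the list alone, with a median of 1.42 (adjusted p = 0.0699 with an estimated correlation). Lep rose by 4.59 ± 0.5 and the cross-linking enzyme Lox by 2.32 ± 0.26. Of 26 matrix genes, 19 rose, 19 adjusted over the list alone, with a median of 1.27 (adjusted p = 0.769 with an estimated correlation). The sterol genes Hmgcs1 (3.16 ± 0.37) and Sc5d (1.95 ± 0.21) rose. Of 23 cholesterol synthesis genes, 14 rose and 1 fell, 16 and 1 adjusted over the list alone, with a median of 0.97 (adjusted p = 0.723 with an estimated correlation). The B cell gene Ms4a1, which encodes CD20 (chromosome 19, 11249675 to 11266241, minus strand), fell from 138 ± 49.7 to 1.27 ± 0.875 CPM (-6.74 ± 1.61). Of 11 B cell genes, 11 fell, 11 adjusted over the list alone, with a median of -6.74 (adjusted p = 0.778 with an estimated correlation). T cell genes behaved alike, with Cd4 at -5.81 ± 1.22. Of 14 such genes, 13 fell, 13 adjusted over the list alone, with a median of -5.22 (adjusted p = 0.769 with an estimated correlation). Among antigen presentation genes 7 of 8 MHC class II members fell, 7 adjusted over the list alone, with a median of -1.27 (adjusted p = 0.769 with an estimated correlation).

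Glycam1, a gene of lymph node vessels, moved with these lymphocyte genes in the inguinal libraries, from 11992 counts over the 6 mice at 0 days to 3 counts at 12 weeks. Within time points the mean of 7 lymph node stroma genes went with that of 11 B cell genes over mice, at a Pearson r of 0.958 and a Spearman rho of 0.95 (n = 84, both permutation p = 1e-04, one-sided, the smallest that 10000 permutations can give). Without the 2 libraries farthest from the median r was 0.952, and single libraries at 6 weeks held between 0.595 and 236 CPM of Ms4a1. In total 3164 genes were higher and 3399 lower, 3023 at least 2-fold, with adjusted p of at most 0.00044 for the genes named with a fold change. Muscle genes, foreign to fat, were uneven as well. Of 16 skeletal muscle genes, 3 rose, 2 adjusted over the list alone, with a median of 1.04 (adjusted p = 0.769 with an estimated correlation). All 16 rose, with a median of 3.68 once the least correlated library of each time point was left out, replicate 6 at 0 days and replicate 2 at 12 weeks. After 1 week 1213 genes were higher and 554 lower, among them the imprinted gene Mest (2.87 ± 0.63) and, downwards, the detoxifying gene Cyp2f2 (-2.44 ± 0.64). Offsets for GC content and transcript length gave 468 calls, 325 of them among these, and a fit of those 12 libraries alone 57.

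**Figure D1:**
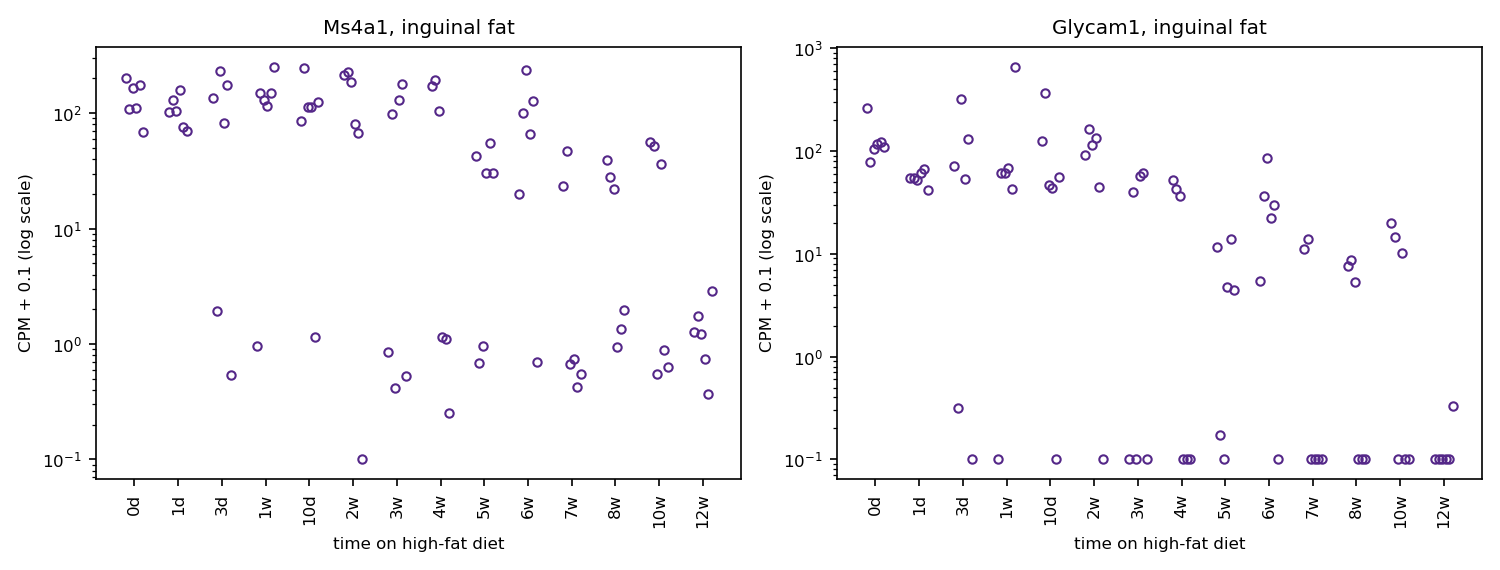
Ms4a1 (B cells) and Glycam1 (lymph node vessels) in inguinal fat, in CPM plus 0.1 on a log axis, at each time on the diet, with 1 circle per mouse. At 0 days all 6 mice held 68.7 to 200 CPM of Ms4a1, at intermediate times single mice ranged from near 0 to over 200 CPM, and at 12 weeks all 6 held 0.266 to 2.77 CPM.

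In brown fat, the heat-producing depot, leptin and inflammatory genes rose over 12 weeks. Lep rose from 6.35 ± 1.96 to 194 ± 77.5 CPM (4.93 ± 0.55) and the calcium channel gene Ryr2 by 4.85 ± 0.3. The lactate receptor gene Hcar1 (-3.58 ± 0.4), the tight junction gene Cldn1 (-4.5 ± 0.51) and Cyp2e1 (-4.76 ± 0.46) fell. Thermogenic genes went both ways, Fgf21 up at 3.82 ± 0.71 and the potassium channel gene Kcnk3 down at -1.19 ± 0.15. Of 18 such genes, 4 rose and 6 fell, 4 and 6 adjusted over the list alone, with a median of -0.11 (adjusted p = 0.922 with an estimated correlation). Of inflammatory genes the acute phase gene Saa3 rose by 4.3 ± 0.85 and Ccl2 by 3.73 ± 0.92. Of 16 cytokine and chemokine genes, 9 rose, 10 adjusted over the list alone, with a median of 2.31 (adjusted p = 0.572 with an estimated correlation). The macrophage gene Ctss rose by 1.07 ± 0.28. Of 19 such genes, 12 rose, 13 adjusted over the list alone, with a median of 0.78 (adjusted p = 0.572 with an estimated correlation). Mki67 rose by 2.05 ± 0.42 and 11 of 20 cell cycle genes rose, 12 adjusted over the list alone, with a median of 0.78 (adjusted p = 0.572 with an estimated correlation). Altogether 1900 genes were higher and 1737 lower (1786 higher and 2382 lower with offsets for GC content and length), 870 at least 2-fold, with adjusted p of at most 0.0019 for the genes named. At 1 week 2077 genes were called, and 8 of 12 heat shock genes rose, 9 adjusted over the list alone, with a median of 0.93 (adjusted p = 0.225 with an estimated correlation). The pacemaker channel gene Hcn2 (3.4 ± 0.29) and Ak4, of mitochondrial energy transfer (3.2 ± 0.33), were higher. The count was 3352 without the least correlated library of each time point, replicate 6 at both 0 days and 1 week.

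In pancreas, hormone genes of the islets rose at 12 weeks. The insulin gene Ins1 (chromosome 19, 52264297 to 52265476, plus strand) rose from 123 ± 32.7 to 373 ± 143 CPM (1.6 ± 0.26). Iapp, the amyloid peptide released with insulin, rose from 42.7 ± 10.3 to 147 ± 53.5 CPM (1.79 ± 0.24) and the islet glucose phosphatase G6pc2 by 1.52 ± 0.22. All 6 mice at 12 weeks lay above all 6 at 0 days for Ins1 and Iapp. Of the islet list 9 of 24 members rose, 17 adjusted over the list alone, with a median of 0.88 (adjusted p = 0.019 with an estimated correlation). Of exocrine genes Sycn, of zymogen granules, rose (1.29 ± 0.23) and the granule membrane gene Gp2 fell (-1.35 ± 0.15). Lep (3.51 ± 0.8) and Cfd (-3.26 ± 0.68), both adipocyte genes, moved in opposite directions (adjusted p 0.00077 to 0.12 and 0.00011 to 0.086 over the alternatives, the highest by voom with quality weights). Of 16 adipocyte genes, 2 rose and 1 fell, 3 and 1 adjusted over the list alone, with a median of 0.14 (adjusted p = 0.818 with an estimated correlation). Of 12391 genes 353 were higher and 378 lower, 200 at least 2-fold, at adjusted p of at most 0.0024 for those named.

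The small intestine raised genes of fatty acid oxidation. Cyp4a10, a fatty acid hydroxylase (chromosome 4, 115518264 to 115533649, plus strand), rose from 10.5 ± 1.96 to 69.8 ± 5.58 CPM (2.75 ± 0.18) and the fatty acid binding protein gene Fabp1 by 1.08 ± 0.08. Of 28 PPAR target and fatty acid oxidation genes, 19 rose and 2 fell, 19 and 2 adjusted over the list alone, with a median of 0.46 (adjusted p = 0.323 with an estimated correlation). The drug-metabolising gene Cyp2c29 fell (-4.99 ± 0.24) and the MHC gene H2-Q10 rose (3.97 ± 0.2). Resident macrophage genes rose, Csf1r by 0.49 ± 0.05 and C1qc by 0.7 ± 0.07. Of 19 such genes, 13 rose and 1 fell, 15 and 1 adjusted over the list alone, with a median of 0.4 (adjusted p = 0.0299 with an estimated correlation). All measured class II genes rose, Cd74 by 0.73 ± 0.1. Of 8 such genes, 8 rose, 8 adjusted over the list alone, with a median of 0.51 (adjusted p = 0.351 with an estimated correlation). Sterol genes such as Stard4 (-0.52 ± 0.06) mostly fell. Of 24 members of the cholesterol synthesis list, 3 rose and 13 fell, 3 and 13 adjusted over the list alone, with a median of -0.24 (adjusted p = 0.614 with an estimated correlation). Genes of pancreas and fat moved in the same libraries. Of 25 pancreatic acinar genes, 25 fell, 25 adjusted over the list alone, with a median of -3.93 (adjusted p = 0.351 with an estimated correlation). Of 16 adipocyte genes, 2 rose and 8 fell, 2 and 8 adjusted over the list alone, with a median of -0.52 (adjusted p = 0.614 with an estimated correlation), and 1 rose with offsets for GC content and length. Pla2g1b stood at -4.76 ± 0.65, Adipoq at -3.34 ± 0.36 and Cfd at -6.4 ± 0.5, and Slc10a2, the bile acid transporter of the ileum, at -0.81 ± 0.14. Of 10 genes that differ between regions of the intestine, 1 rose and 5 fell, 1 and 5 adjusted over the list alone, with a median of -0.31 (adjusted p = 0.4 with an estimated correlation). At 12 weeks 2839 genes were higher and 2744 lower, 393 at least 2-fold, with adjusted p of at most 2.3e-06 for those named. After 1 week 3879 genes were called, 2515 with offsets for GC content and length; H2-Q10 (4.41 ± 0.2) was already higher and Cyp2c29 (-5.69 ± 0.27) and Cyp2c55 (-4.46 ± 0.18) lower.

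Both muscles raised genes of fatty acid oxidation. In gastrocnemius Hadhb, a subunit of the mitochondrial trifunctional protein (chromosome 5, 30155248 to 30184593, plus strand), rose from 214 ± 23.2 to 416 ± 53.5 CPM (0.96 ± 0.11), the dehydrogenases Acadl and Acadvl by 0.88 ± 0.08 and 0.67 ± 0.09, and the peptide hormone gene Ostn by 2.79 ± 0.25. Of PPAR targets and genes of fatty acid oxidation 15 of 28 members rose, 16 and 1 lower adjusted over the list alone, with a median of 0.64 (adjusted p = 0.000933 with an estimated correlation). At 1 week 7 of 28 rose, 15 adjusted over the list alone, with a median of 0.43 (adjusted p = 0.00531 with an estimated correlation), and 12 rose with offsets for GC content and length. The collagen gene Col1a1 fell (-2.27 ± 0.39). Of 26 matrix genes, 8 fell, 9 adjusted over the list alone, with a median of -0.47 (adjusted p = 0.284 with an estimated correlation). Soleus, the slower muscle, raised Hadhb by 1.12 ± 0.17 and Cpt2, of carnitine transport, by 0.89 ± 0.18. Of 26 members of the same list, 10 rose and 1 fell, 15 and 3 adjusted over the list alone, with a median of 0.63 (adjusted p = 0.0264 with an estimated correlation). The acetylcholine receptor gene Chrna2 (chromosome 14, 66135039 to 66152948, plus strand) rose in soleus from 3.34 ± 1.71 to 24.3 ± 3.78 CPM (2.83 ± 0.24). Of 13 fast fibre genes, 3 fell, 5 adjusted over the list alone, with a median of -1.22 (adjusted p = 0.00766 with an estimated correlation). The calsequestrin gene Casq1 stood at -0.72 ± 0.17 (adjusted p up to 0.22 over the alternatives, the highest in a fit of the 12 libraries alone and 0.068 with offsets for GC content and length). Of 12 heat shock genes, 4 rose, 5 adjusted over the list alone, with a median of 0.39 (adjusted p = 0.0264 with an estimated correlation). Of 19 unfolded protein response genes, 3 rose, 5 adjusted over the list alone, with a median of 0.24 (adjusted p = 0.0264 with an estimated correlation). With offsets for GC content and length 16 genes of fatty acid oxidation rose and 6 of fast fibres fell. The adipocyte genes Lep and Cfd moved in both muscles, Lep at 3.29 ± 0.57 and Cfd at -2.82 ± 0.45 in gastrocnemius, and at 2.71 ± 0.75 and -2.45 ± 0.61 in soleus; without the least correlated library of each time point, replicate 2 at both, Cfd in gastrocnemius stood at -1.72. Soleus had 287 genes higher and 221 lower, 248 at least 2-fold, and gastrocnemius 315 and 464, 238 at least 2-fold, with adjusted p of at most 0.022 for those named. The counts moved with the method: a fit of the 12 libraries alone called 188 genes in soleus and 2835 in gastrocnemius, and offsets for GC content and length 1101 and 1411. In gastrocnemius the balance turned, with 806 higher and 605 lower under the offsets and 1456 higher and 1379 lower in the fit of the 12 libraries. Of 30 splits of the 12 soleus libraries 2, the real one included, gave at least as many calls as the real one, so the soleus counts at 12 weeks are not shown to exceed chance by that test.

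**Figure D2:**
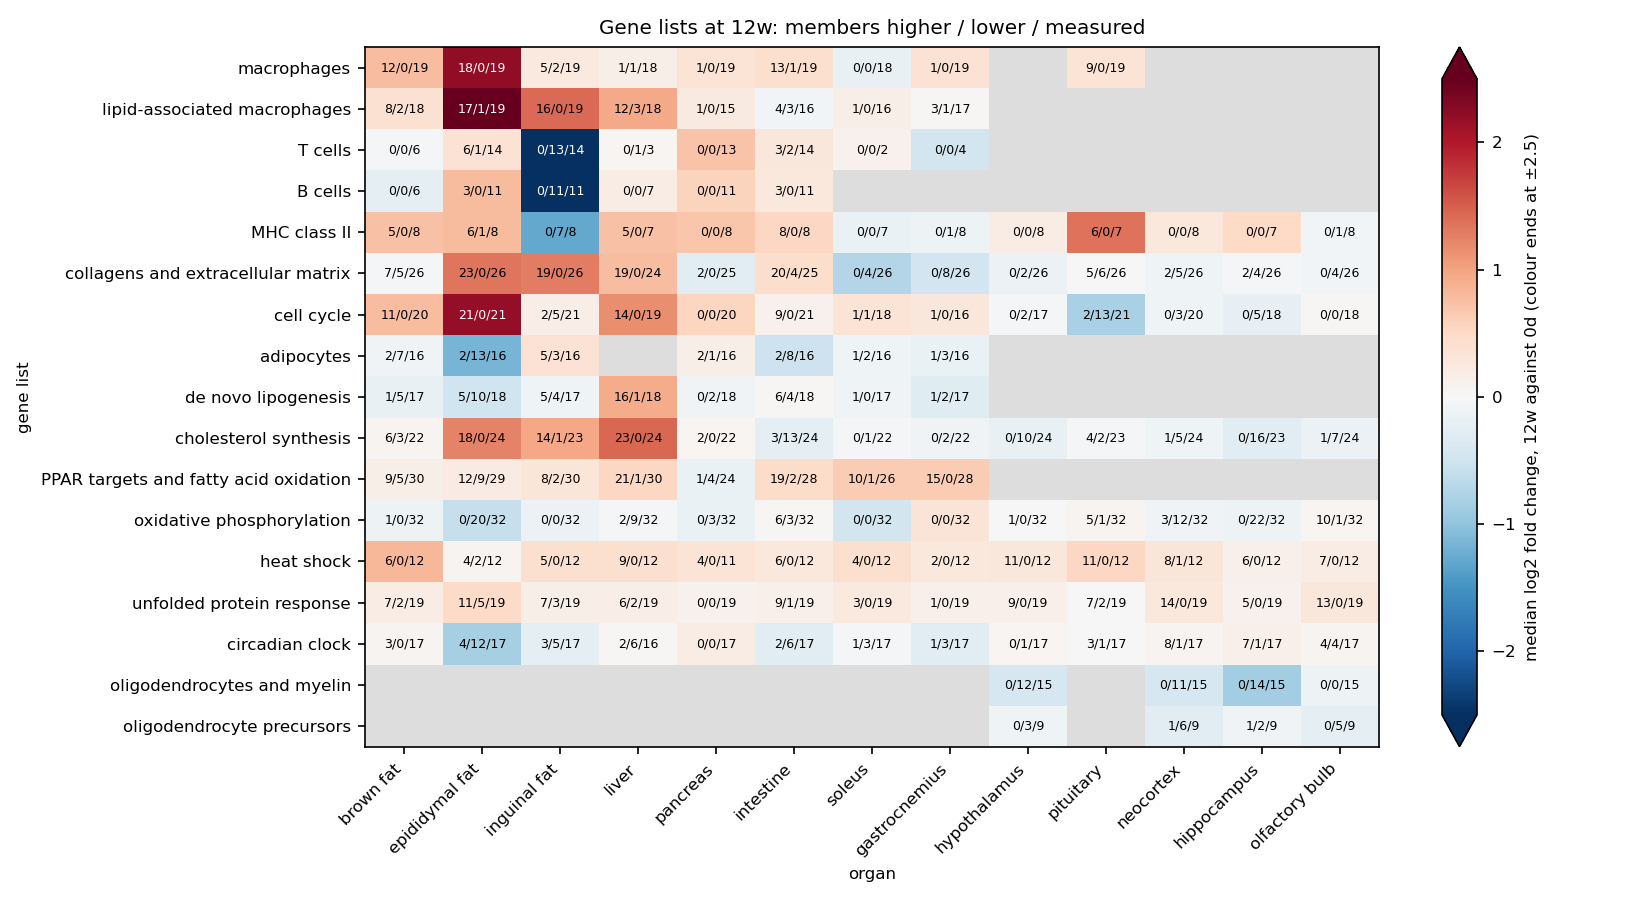
Median log2 fold change at 12 weeks against 0 days of 17 of the fixed gene lists (colour, which ends at ±2.5), with organs as columns and lists as lines, where each field gives the members higher, lower and measured, and grey fields were not tested. B cell genes in inguinal fat have a median of -6.74, macrophage genes in epididymal fat of 2.22, cholesterol synthesis genes in liver of 1.43, and myelin genes of -0.41 in hypothalamus, -0.41 in neocortex and -0.87 in hippocampus.

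Myelin genes fell in 3 brain regions. Mog, a protein of the myelin surface (chromosome 17, 37010743 to 37023398, minus strand), went from 80.3 ± 9 to 34.2 ± 2.03 CPM in hippocampus (-1.23 ± 0.11) and from 66.2 ± 3.4 to 36.8 ± 2.73 CPM in neocortex (-0.85 ± 0.06). In both, all 6 mice at 12 weeks lay below all 6 at 0 days, and in hypothalamus it stood at -0.67 ± 0.06. Enpp6, a marker of newly forming oligodendrocytes, fell as well (-1.25 ± 0.17, -1.01 ± 0.11 and -1 ± 0.1 in the same order), and in the olfactory bulb (-0.62 ± 0.13). Of the myelin list 14 of 15 members fell, 15 adjusted over the list alone, with a median of -0.87 (adjusted p = 0.0292 with an estimated correlation) in hippocampus. Of 15 such genes, 11 fell, 11 adjusted over the list alone, with a median of -0.41 (adjusted p = 0.00843 with an estimated correlation) in neocortex. Of 15 such genes, 12 fell, 13 adjusted over the list alone, with a median of -0.41 (adjusted p = 0.000219 with an estimated correlation) in hypothalamus. Of 9 genes of oligodendrocyte precursors, 3 fell, 4 adjusted over the list alone, with a median of -0.11 (adjusted p = 7.63e-05 with an estimated correlation) in hypothalamus. Of 9 such genes, 1 rose and 6 fell, 1 and 6 adjusted over the list alone, with a median of -0.26 (adjusted p = 0.00843 with an estimated correlation) in neocortex. Of 9 such genes, 5 fell, 5 adjusted over the list alone, with a median of -0.23 (adjusted p = 0.0319 with an estimated correlation) in the olfactory bulb. Of 9 such genes, 1 rose and 2 fell, 2 and 2 adjusted over the list alone, with a median of -0.08 (adjusted p = 0.594 with an estimated correlation) in hippocampus.

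In hippocampus sterol synthesis fell with myelin, Hmgcs1 at -0.36 ± 0.05 and Sqle at -0.37 ± 0.06. Of 23 cholesterol synthesis genes, 16 fell, 17 and 1 higher adjusted over the list alone, with a median of -0.27 (adjusted p = 0.0231 with an estimated correlation). The genes Igfbpl1 (-1.91 ± 0.23) and Dcx (-0.42 ± 0.09) of newborn neurons fell. Of 14 newborn neuron genes, 6 fell, 6 adjusted over the list alone, with a median of -0.16 (adjusted p = 0.0802 with an estimated correlation), and 3 fell with offsets for GC content and length. Respiratory chain genes were slightly lower. Of 32 such genes, 22 fell, 24 adjusted over the list alone, with a median of -0.13 (adjusted p = 0.0333 with an estimated correlation), but with the offsets 2 rose and 2 fell. Of 12 genes of the reference list, 5 fell, 6 adjusted over the list alone, with a median of -0.08 (adjusted p = 0.0333 with an estimated correlation). The deiodinase gene Dio2 rose by 0.9 ± 0.09. Hippocampus had 1960 genes higher and 1838 lower, only 58 at least 2-fold, and with those offsets 1636 higher and 785 lower. In neocortex the stress chaperone gene Hspa1b rose by 1.27 ± 0.14 and the activity gene Egr3 by 0.64 ± 0.07. Of 19 unfolded protein response genes, 14 rose, 15 adjusted over the list alone, with a median of 0.27 (adjusted p = 0.0588 with an estimated correlation). Of 16 immediate early genes, 10 rose, 14 adjusted over the list alone, with a median of 0.66 (adjusted p = 0.118 with an estimated correlation). The microglial gene Cx3cr1 fell (-0.43 ± 0.06). Of 16 microglial genes, 7 fell, 8 adjusted over the list alone, with a median of -0.21 (adjusted p = 0.118 with an estimated correlation). There 1973 genes were higher and 1747 lower, 51 at least 2-fold, and with the offsets 2236 higher and 1130 lower. The genes named in both regions had adjusted p of at most 0.00027. At 1 week 1344 genes were called in neocortex and 824 with the offsets, Hspa1b at 0.87 ± 0.15 among them.

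In hypothalamus, which controls feeding, the orexigenic peptide gene Npy (chromosome 6, 49822710 to 49829507, plus strand) fell from 11.4 ± 2.07 to 7.58 ± 0.339 CPM (-0.59 ± 0.14). The satiety precursor gene Pomc (chromosome 12, 3954951 to 3960642, plus strand) rose from 16.6 ± 4.95 to 25.2 ± 1.77 CPM (0.61 ± 0.15). These stood within a list in which 2 of 26 neuropeptide and receptor genes rose and 1 fell, 5 and 2 adjusted over the list alone, with a median of 0.13 (adjusted p = 0.595 with an estimated correlation). Chaperone genes rose, Chordc1 by 0.35 ± 0.05 and Hspa8 by 0.18 ± 0.03. Of 12 heat shock genes, 11 rose, 12 adjusted over the list alone, with a median of 0.28 (adjusted p = 0.00418 with an estimated correlation). Of 19 unfolded protein response genes, 9 rose, 11 adjusted over the list alone, with a median of 0.12 (adjusted p = 0.00625 with an estimated correlation). Sterol synthesis fell, Hmgcs1 at -0.24 ± 0.03. Of 24 such genes, 10 fell, 14 adjusted over the list alone, with a median of -0.18 (adjusted p = 0.00639 with an estimated correlation). The lipid transporter Abca8a rose by 1.29 ± 0.09. Changes were small, with 465 genes higher and 557 lower but 21 at least 2-fold, and adjusted p of at most 0.005 for those named; a fit of the 12 libraries alone called 613, and with offsets for GC content and length 547 were higher and 419 lower. At 1 week 104 genes were called, 68 with offsets and 7 in a fit of 12 libraries, the clock gene Ciart at -0.51 ± 0.11 (adjusted p 0.0012 to 0.059 over the alternatives, the highest in the smaller fit).

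The olfactory bulb raised chaperone genes at 12 weeks. Hspb1, a small heat shock protein (chromosome 5, 135887919 to 135889563, plus strand), went from 6.32 ± 0.902 to 12.8 ± 1.53 CPM (1.01 ± 0.12), Sdf2l1 rose by 0.96 ± 0.15 and Xbp1, a regulator of the unfolded protein response, by 0.55 ± 0.07. Of 19 genes of that response, 13 rose, 14 adjusted over the list alone, with a median of 0.29 (adjusted p = 0.0608 with an estimated correlation). Of 12 heat shock genes, 7 rose, 7 adjusted over the list alone, with a median of 0.19 (adjusted p = 0.427 with an estimated correlation). The sialyltransferase gene of young neurons St8sia2 (-0.92 ± 0.17) and the transcriptional corepressor Lcor (-0.88 ± 0.12) fell. The bulb had 1615 genes higher and 1492 lower, 59 at least 2-fold, with adjusted p of at most 3.1e-05 for those named, and 1621 calls with offsets for GC content and length. At 1 week 584 genes were called, 59 with the offsets; Hspb1 was at 0.74 ± 0.12 and Lcor at -0.64 ± 0.12.

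In the pituitary gland, growth hormone mRNA was lower after 12 weeks. Gh (chromosome 11, 106300271 to 106301865, minus strand) fell from 163000 ± 17300 to 83000 ± 8090 CPM (-0.97 ± 0.12) and Ghrhr, the receptor that drives its release, stood at -1.02 ± 0.12, while the prohormone convertase Pcsk1 rose by 0.72 ± 0.08. For Gh all 6 mice at 12 weeks lay below all 6 at 0 days. Of the hormone list 6 of 21 members rose and 5 fell, 7 and 5 adjusted over the list alone, with a median of 0.13 (adjusted p = 0.927 with an estimated correlation); its mean was below 0 (-0.03). Class II genes rose, H2-Aa by 1.4 ± 0.12 and Cd74 by 1.35 ± 0.13. Of 7 such genes, 6 rose, 6 adjusted over the list alone, with a median of 1.35 (adjusted p = 0.352 with an estimated correlation). Division genes fell, Mki67 at -1.02 ± 0.21 and Ccnb2 at -1.78 ± 0.32. Of 21 such genes, 2 rose and 13 fell, 2 and 15 adjusted over the list alone, with a median of -0.81 (adjusted p = 0.765 with an estimated correlation), and 1 rose with offsets for GC content and length. Heat shock genes rose, Hspb1 by 1.12 ± 0.14. Of 12 such genes, 11 rose, 11 adjusted over the list alone, with a median of 0.52 (adjusted p = 0.616 with an estimated correlation). Lcor rose by 3.45 ± 0.14 and Mlxipl stood at -1.93 ± 0.14. At 12 weeks 3503 genes were higher and 3375 lower, 736 at least 2-fold, with adjusted p of at most 2.3e-05 for those named; across all genes, which are not independent replicates, fold change and GC content correlated at a Spearman rho of -0.431. At 1 week 3221 genes were higher and 2972 lower, Lcor at 3.31 ± 0.14. Mobp of myelin (6.24 ± 1.02) rested on replicate 2 at 1 week and stood at 0.1 without the least correlated library per time point.

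Pancreas, soleus and hippocampus had few calls after 1 week. The nuclear protein gene Tspyl2 (-1.07 ± 0.21) and Myc (-0.92 ± 0.18) were lower in pancreas, Chrna2 (2.09 ± 0.24) was higher and Nr1d1, of the clock, lower (-1 ± 0.22) in soleus, and the activity gene Egr4 (-0.62 ± 0.12) was lower in hippocampus. Pancreas had 24 calls (9 higher), soleus 14 (9 higher) and hippocampus 61 (47 higher), with adjusted p of at most 0.025 for those named, beside 1616, 1196 and 1598 at an unadjusted p under 0.05. A fit by edgeR of the 12 libraries alone called 0 in each (867, 978 and 1373 unadjusted), and DESeq2 called 83, 46 and 107. Gastrocnemius had 45 genes higher and 120 lower at 1 week, with the clock gene Ciart at -1.42 ± 0.29 and Decr1, of fatty acid oxidation, at 0.76 ± 0.11. Offsets for GC content and length gave 131 higher and 137 lower in gastrocnemius, 1 higher and 6 lower in pancreas and 52 higher and 16 lower in soleus. Without the least correlated library of each time point the counts were 778 in pancreas (replicate 6 at 0 days, 5 at 1 week), 44 in soleus (1 and 4), 7 in hippocampus (5 and 3) and 340 in gastrocnemius (2 and 6).

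Whether the 12-week change differed between organs was tested within the white fat depots and within the muscles. Between the depots (epididymal minus inguinal) the lymphocyte genes Il7r (8.03 ± 0.32) and Cd22 (9.76 ± 0.44) and the cannabinoid receptor of immune cells Cnr2 (5.63 ± 0.27) differed upwards, and the positional gene Hoxa7 (-2.03 ± 0.1) and the smooth muscle genes Acta2 (-2.82 ± 0.18) and Myl9 (-2.51 ± 0.17) downwards. The lymphocyte genes are those that fell with Glycam1 in the inguinal libraries. Of 14666 genes 8230 differed, 4479 upwards and 3751 downwards, or 4052 and 4178 with RLE size factors. Between the muscles (soleus minus gastrocnemius) the embryonic actin gene Actc1 (2.44 ± 0.38) and the growth factor gene Ccn2 (2.03 ± 0.33) differed upwards and Myod1, a regulator of muscle identity, downwards (-2.64 ± 0.21). There 34 of 12688 genes differed, 12 upwards and 22 downwards. With the replicate number as a block 7 differed, all of them among the 34, and without a filter on low counts 24. DESeq2 called 142, offsets for GC content and length gave 175, and 1 library fewer per group 69 (without replicate 1 at 0 days and 6 at 12 weeks of soleus, and replicate 2 at both in gastrocnemius). Adjusted p was at most 0.0049 for the genes named.

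Over the whole course the organs differed in when calls appeared. In epididymal fat 2895 genes were called after 1 day, 5774 after 3 days and 8136 at 7 weeks, and in liver 1215 after 1 day and 3825 at 8 weeks. The pituitary went from 22 after 1 day to 6033 after 3 days, whereas edgeR called 0 genes in the olfactory bulb after 1 day (802 unadjusted). Gastrocnemius had 2972, 5254 and 4095 calls at 2, 3 and 10 weeks but 236 at 5 weeks. With 1 library fewer per time point (replicates 6, 3 and 4) the counts at 2, 3 and 10 weeks were 938, 3910 and 2741. The balance turned from 1888 higher and 1084 lower to 323 and 615 at 2 weeks, and from 2219 and 1876 to 1264 and 1477 at 10 weeks. The bulb had 5956 calls at 4 weeks, and 1 of its 6 libraries there, replicate 6, held 0.26 CPM of Dlx1, a gene of bulb interneurons, against 377 to 404 in the other 5. Without the least correlated library per time point 5114 were called.

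Slopes on log2 days over 1 day to 10 weeks, from libraries of neither the 0-day nor the 12-week group, mostly had the sign of the 12-week change. The share of 12-week calls whose slope had that sign, with a permutation p, was 98.4% in pituitary (p = 0.0005), 97.9% in inguinal fat (p = 0.0081), 97.7% in olfactory bulb (p = 0.0009), 96.8% in soleus (p = 0.0017), 96.6% in hypothalamus (p = 0.0001) and 95.8% in gastrocnemius (p = 0.0003). By the same permutation test it was 90% in epididymal fat (p = 0.0251), 88.4% in liver (p = 0.0055), 88.1% in pancreas (p = 0.0085), 87.2% in hippocampus (p = 0.0183), 85.3% in neocortex (p = 0.0154), 85.1% in brown fat (p = 0.0408) and 83.7% in small intestine (p = 0.0018). Each p comes from a one-sided permutation of the time points, drawn 10000 times, and 1e-04 is the smallest they can give. Among the genes named, Cidec in liver stood at 5.44 CPM at 4 weeks and Itgax in epididymal fat at 23.1 CPM.

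**Figure D3:**
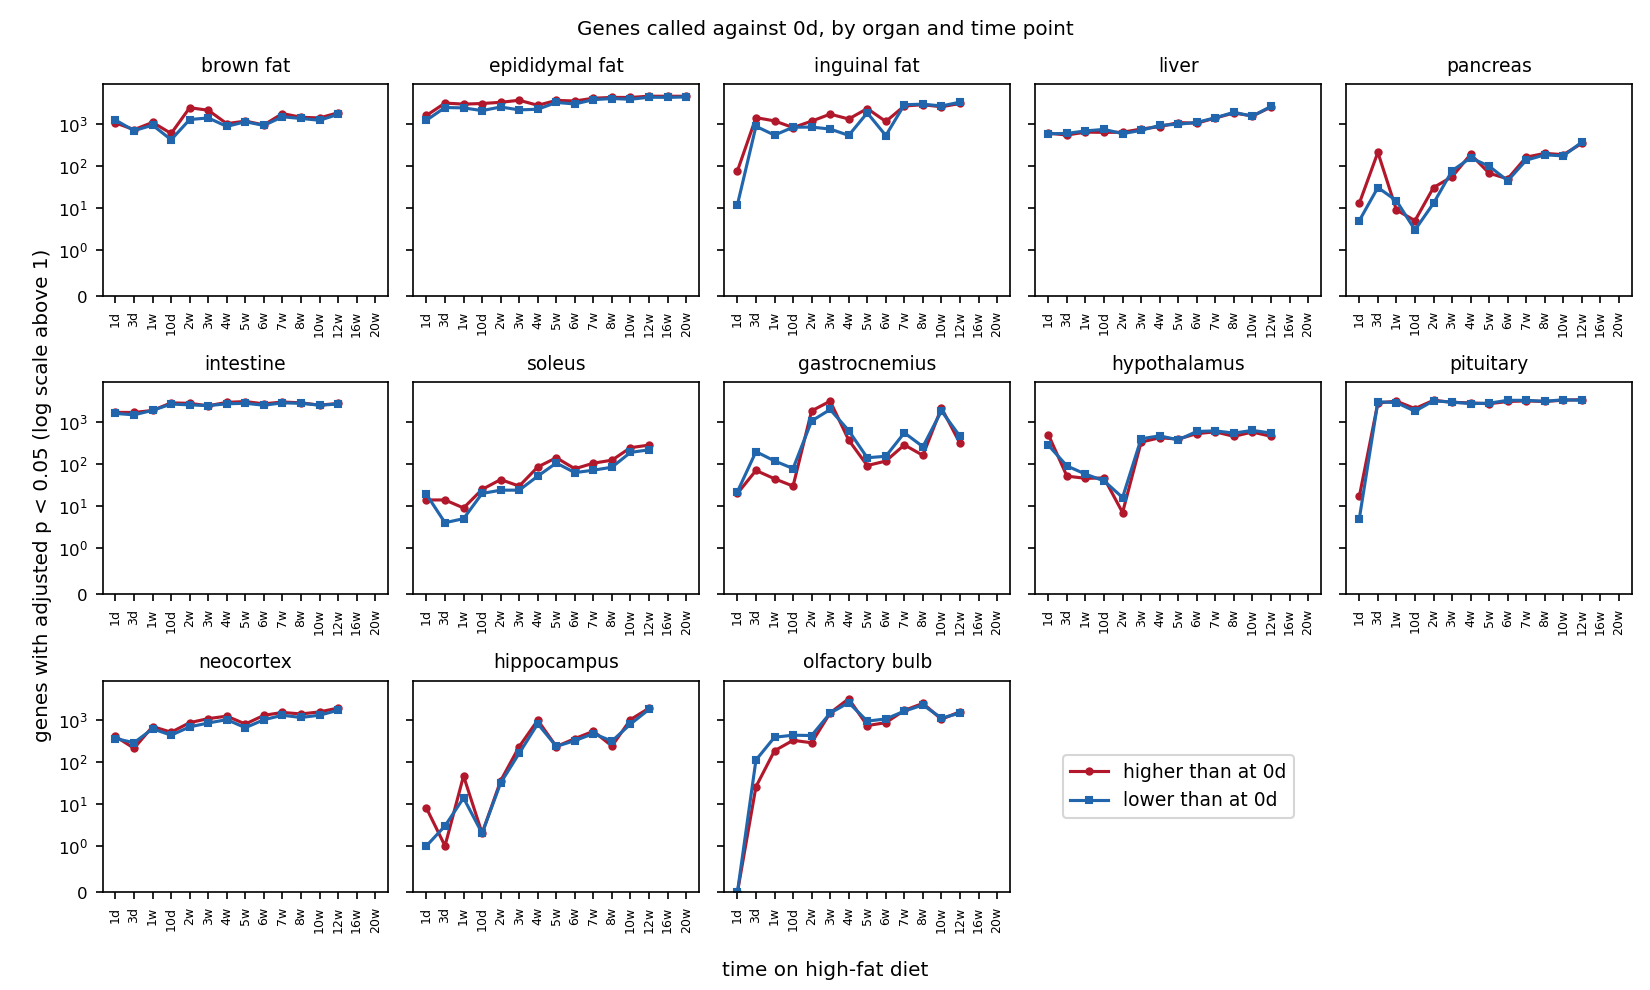
Number of genes called higher (red circles) and lower (blue squares) than at 0 days at each time on the diet, with 1 panel per organ and a y axis that is logarithmic above 1. The pituitary steps from 17 higher and 5 lower at 1 day to 2920 and 3113 at 3 days, and gastrocnemius peaks at 3218 and 2036 at 3 weeks.

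**Figure D4:**
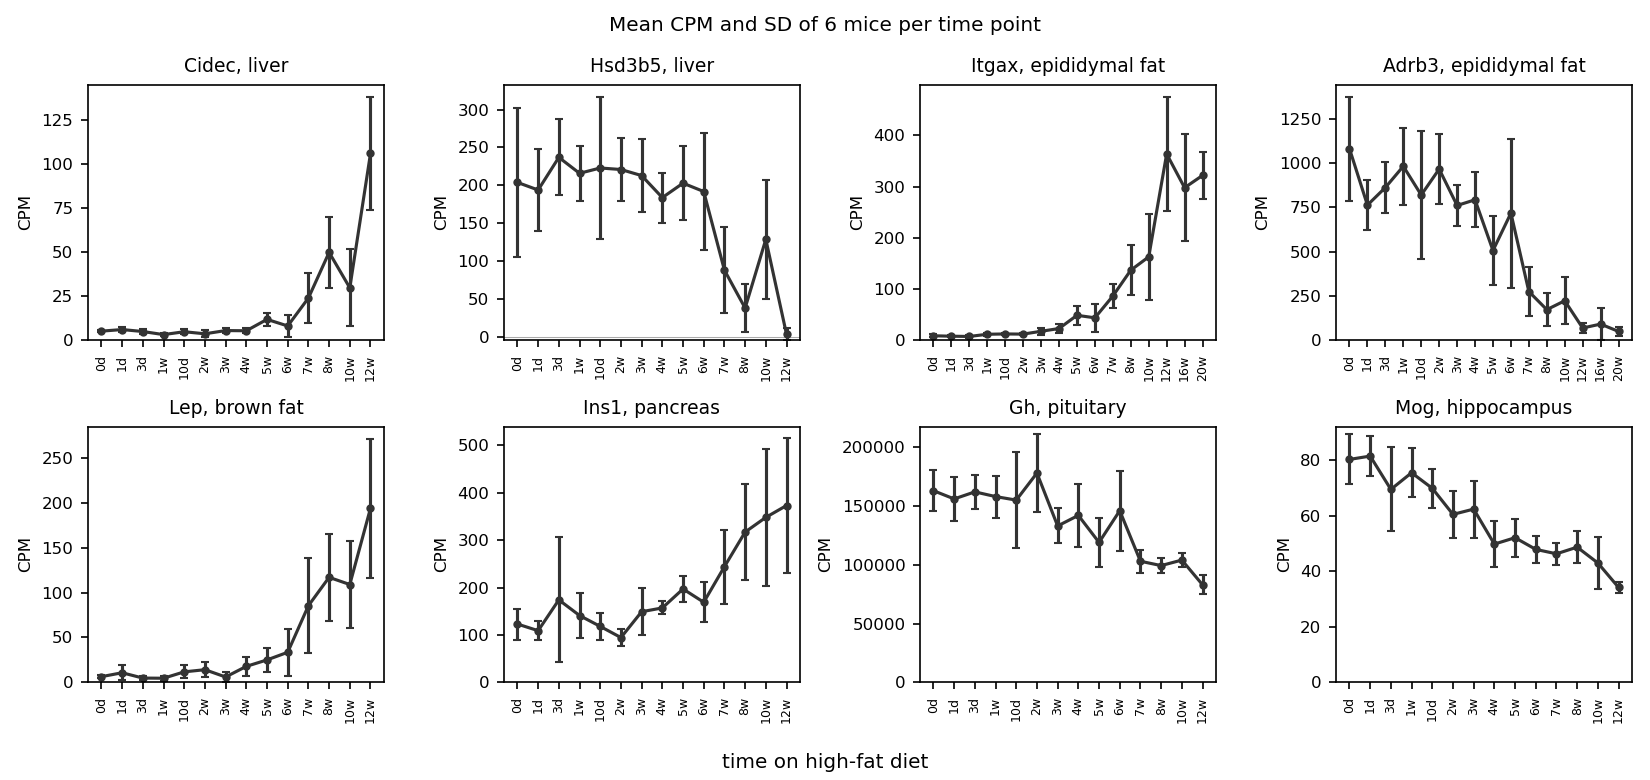
Level in CPM of 8 genes at each time on the diet, as the mean (points joined by a line) and SD (bars) of 6 mice: Cidec and Hsd3b5 in liver, Itgax and Adrb3 in epididymal fat, Lep in brown fat, Ins1 in pancreas, Gh in pituitary and Mog in hippocampus. Cidec reaches 106 ± 32.3 CPM at 12 weeks from 5.23 ± 0.542, and Mog ends at 34.2 ± 2.03 from 80.3 ± 9.

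Spread between mice was compared between time points, since the series looks for fluctuation ahead of disease. In gastrocnemius at 3 weeks the lipoprotein lipase gene Lpl deviated from its time point mean by 1.03 against 0.177 at the other times, a difference of 0.86 ± 0.078 (log2 CPM). In hippocampus at 10 weeks the histone methyltransferase gene Kmt2d deviated by 0.322 against 0.0426 at the other times, a difference of 0.28 ± 0.019. Fasn in pancreas at 3 days deviated by 0.813 against 0.162 at the other times, a difference of 0.65 ± 0.079. Phf7 in epididymal fat at 3 weeks deviated by 1.67 against 0.19 at the other times, a difference of 1.48 ± 0.17. By limma (one-sided) the gene and time point pairs with higher spread numbered 21931 in gastrocnemius, 20019 in epididymal fat, 14482 in soleus, 12871 in inguinal fat, 11125 in brown fat, 7224 in pituitary, 7008 in pancreas, 6349 in olfactory bulb, 2171 in small intestine, 1610 in hippocampus, 1526 in liver, 629 in hypothalamus and 498 in neocortex. Most calls lay at 3 weeks in gastrocnemius (8915) and epididymal fat (7649), 7 weeks in soleus (4739), 2 weeks in brown fat (6047) and pituitary (3353), 1 week in inguinal fat (4111), 3 days in pancreas (4340), 4 weeks in the bulb (6180), 10 weeks in hippocampus (1317) and liver (462), and 0 days in small intestine (736). Peaks depended on the setting. Square roots of the deviations gave more at 3 weeks in soleus (5358 against 4931 at 7 weeks), 3 days in inguinal fat (4980 against 2811 at 1 week) and 2 weeks in liver (126 against 84 at 10 weeks). The replicate block did so for the same times of inguinal fat (5867 against 3515) and liver (440 against 242), and squared deviations for 3 days in small intestine (1573 against 1391 at 0 days). The test is liberal: libraries permuted over time points gave up to 12225 calls in gastrocnemius, 11736 in inguinal fat and 441 in neocortex, and with square roots of the deviations, added after seeing the data, 339 were called in liver and 26 in neocortex, but 22712 in gastrocnemius and 16081 in soleus.

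Several of these peaks rested on 1 library. The bulb genes Dlx1 and Eomes at 4 weeks deviated by 2.76 against 0.0471 at the other times, a difference of 2.71 ± 0.3, and 2.8 against 0.0527 at the other times, a difference of 2.75 ± 0.31. Both differences were -0.01 without replicate 6, when 15 genes were called there. The splicing factor gene Srrm2 in pancreas at 3 days went from a difference of 1.05 to -0.02 and Erg in brown fat at 2 weeks from 1.56 to -0.11 without the least correlated library of each time point (replicate 5 in pancreas, 6 in brown fat), with 36 and 146 calls at those times. By the same step calls went to 2 in inguinal fat at 1 week (without replicate 6), 481 in soleus at 7 weeks (1), 197 in pituitary at 2 weeks (5), 435 in hippocampus and 168 in liver at 10 weeks (1 in both). At other times of these organs it raised the calls, in soleus at 3 weeks from 4574 to 7744, and in inguinal fat from 3887 to 5052 at 3 days and from 943 to 4954 at 10 days. Most calls then lay at 7 weeks in brown fat (1192), 5 weeks in pituitary (1710), 1 week in pancreas (1942), 2 weeks in liver (275), 0 days in the bulb (266), 3 weeks in soleus and 3 days in inguinal fat. Gastrocnemius at 3 weeks had 8133 and epididymal fat 7562. Summed over all genes, spread passed the threshold by permutation at 0 of 184 time points (9 at an unadjusted p under 0.05, one-sided). The share of variation on the first principal component passed at 2, the pituitary at 1 week (53.8%, adjusted p = 0.00184 by permutation) and the olfactory bulb at 4 weeks (80.8%, adjusted p = 0.0377 by permutation). Both rested on 1 library: without replicate 2 and replicate 6, the least correlated there, the shares were 29.1% and 29.3% (adjusted p = 0.999 and 0.873 by permutation). With 1 library fewer at every time point the pituitary passed at 0 days (44.9%, adjusted p = 0.00368) and 5 weeks (42.8%, adjusted p = 0.0414) by permutation.

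**Figure D5:**
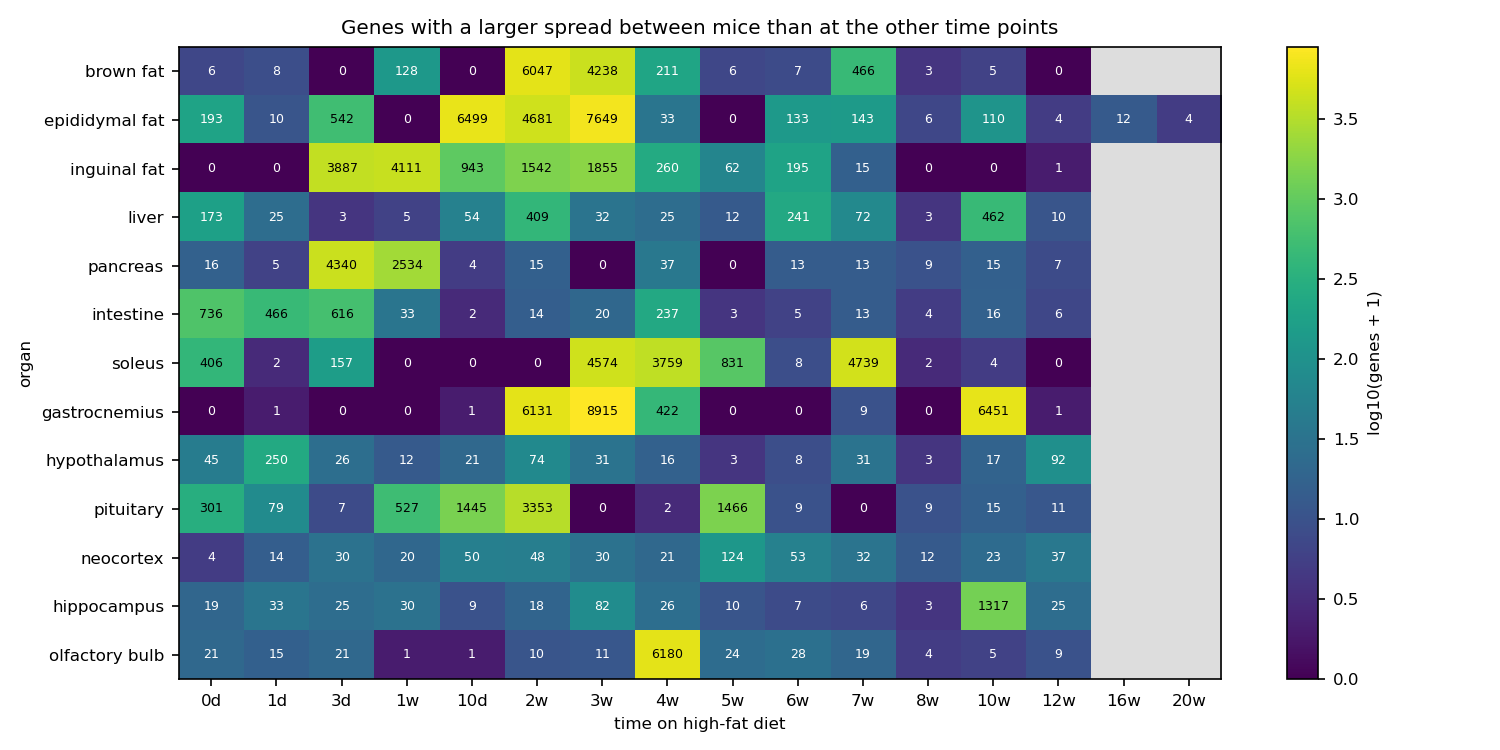
Number of genes with higher spread between the 6 mice of a time point than at the other time points, with organs as lines and times on the diet as columns of a colour map on a log10 scale of the number plus 1, where grey fields have no libraries. Gastrocnemius peaks at 3 weeks with 8915 genes and the olfactory bulb at 4 weeks with 6180, where 15 are called when 1 library of each time point is left out.

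Some genes changed in many organs at 12 weeks. Cirbp, a cold-induced RNA-binding protein, fell in 12 of 13 organs (-1.07 ± 0.12 in pituitary, -0.62 ± 0.15 in liver), and the clock output gene Dbp in 11. The chaperone gene Hsph1 rose in 11 organs, Hspa8, the collagen hydroxylase gene P4ha1 and the glycolytic gene Pgam1 in 10, and the adenylate kinase gene Ak4 and Dnaja1 in 9, while Atxn7l3b and the linker histone gene H1f0 fell in 9. Of 10825 genes tested in all 13 organs, 90 were higher and 44 lower in at least 7 (4 and 2 by 1.5-fold or more). Independent calls would give 5.47 and 3.53 if every gene were as easy to call. That need not hold, so the excess alone shows no shared response.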

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

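Of the tests in this part only the depth of the bulb library, the 1-week and 20-week splits and those of the interactions were set out before their result was seen; the 12-week splits, the permutations for spread and the other tests of the 3 patterns were chosen after it, as was the gene Mobp.

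Hsd3b5 in liver at 12 weeks was set apart because 1 library, replicate 6, lay far above the other 5, at 20.4 CPM. It was the only one of 40 groups past Dixon's limit, where chance flags about 1 in 20 groups. The fat depots differed in their 12-week change by a test of the interaction in 8230 genes, and the muscles in 34.

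The pituitary step between 1 and 3 days was weighed first: edgeR called 22 genes at 1 day and 6033 at 3 days against 0 days, 5726 between 1 and 3 days and 63 between 3 days and 4 weeks, and the mean on the first principal component went from -39.5 at 1 day to 6.44 at 3 days and 14.7 at 12 weeks. GC content and transcript length are unlikely to be the whole cause, since 57.5% of the genes called at 3 days (3471 of 6033) stayed called in the same direction with offsets for both, although the median absolute log2 fold change of the genes called went from 0.39 to 0.24. Library size argues no better, as 87.5% of the later libraries (63 of 72) had totals within the range of those at 0 days and 1 day, 13146637 to 17692139. A library or dissection batch that starts at 3 days cannot be told apart from the diet, since the labels name none and the step follows time in all later libraries but 1. That one, replicate 2 at 10 days, stood at -31.7 on that component, near those of 0 days and 1 day (-45.1 to -35.7) and apart from the other 5 of its group (-12.3 to 1.13), which was not explained; 1755 genes were called between 3 days and 12 weeks, fewer than across the step. Diet and age stay open as untested.

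The lymphocyte genes of inguinal fat were weighed next: within time points 7 lymph node stroma genes and 11 B cell genes went together over mice, with a Pearson r of 0.958 and a Spearman rho of 0.95 (both permutation p = 1e-04, one-sided, n = 84, the smallest they can give), r 0.952 without the 2 farthest libraries, and a mean rho per time point of 0.747. This is what lymph node tissue in part of the libraries would give, which is a candidate source and may have been dissected with the fat to a varying extent; lymphoid tissue formed in the fat would do the same. A steady loss from the start of the diet is argued against by 13 of 48 libraries from 2 to 10 weeks that reached the lowest 0-day level of Ms4a1, 68.7 CPM, as 4 of 6 did at 2 weeks. No library of those at 5, 7, 8 and 10 weeks did, so a decline at later times stays open.

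Replicate 6 of the olfactory bulb at 4 weeks was weighed last: over the 1000 genes that differ most between brain regions it correlated with the hypothalamus mean at 0.581, and with the bulb mean at -0.235, whereas the other 335 of 336 brain libraries correlated best with their own region. Tissue from another region than the bulb is therefore a likely source, since the bulb genes Eomes (0 against 149 to 162 CPM in the other 5) and Sp8 (0.19 against 175 to 198) were near absent and the myelin gene Mobp was high (1800 against 324 to 394). Low depth is argued against by a total of 16129694, inside the range of the other bulb libraries, 10532464 to 20875631. A swap with a hypothalamus library of the series would need a partner, and 0 of 84 hypothalamus libraries correlated best with the bulb. Without the least correlated library of each time point the bulb had 5114 calls at 4 weeks in place of 5956; no biological explanation was tested.

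Random splits of the same libraries, 30 with the real one, were fitted with the 2 groups alone. A value of 1 of 30 is the smallest they can give. The values were not adjusted over the comparisons, so 1 of 30 does not by itself exclude chance. At 12 weeks no other split gave as many calls (value 1 of 30) for 5336 in brown fat (highest other 0), 9619 in epididymal fat (highest other 0), 8344 in inguinal fat (highest other 0), 4986 in liver (highest other 0), 870 in pancreas (highest other 25), 4884 in small intestine (highest other 0), 2835 in gastrocnemius (highest other 1), 613 in hypothalamus (highest other 1), 7329 in pituitary (highest other 2), 3864 in neocortex (highest other 0), 3498 in hippocampus (highest other 328) and 3748 in olfactory bulb (highest other 0). In soleus 2 of 30 did, as the real split gave 188 and another 4728, so chance is not excluded for the 12-week calls of soleus.

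At 1 week no other split gave as many calls (1 of 30) for 3079 in brown fat (highest other 13), 6472 in epididymal fat (highest other 0), 57 in inguinal fat (highest other 0), 1184 in liver (highest other 0), 2954 in small intestine (highest other 0), 237 in gastrocnemius (highest other 0), 7 in hypothalamus (highest other 4), 5488 in pituitary (highest other 0), 1284 in neocortex (highest other 12) and 838 in olfactory bulb (highest other 13). For pancreas, soleus and hippocampus the splits decide nothing, since the real one gave 0 calls in a fit of 12 libraries by edgeR (867, 978 and 1373 genes at an unadjusted p under 0.05; DESeq2 on all libraries 83, 46 and 107), so that 30 of 30 must give as many. Chance was not tested for the 24, 14 and 61 calls of the fits on all libraries. The highest other splits were 0, 0 and 118. Nor did another split give as many calls (1 of 30) for epididymal fat at 20 weeks (10067, highest other 0), the fat interaction (8230, highest other 2661) and the muscle interaction (34, highest other 0). For spread, none of the 40 permutations of libraries over time points gave as many calls (1 of 41) for 11125 in brown fat (highest other 6826), 20019 in epididymal fat (highest other 10235), 12871 in inguinal fat (highest other 11736), 1526 in liver (highest other 320), 7008 in pancreas (highest other 4583), 2171 in small intestine (highest other 749), 14482 in soleus (highest other 11402), 21931 in gastrocnemius (highest other 12225), 629 in hypothalamus (highest other 446), 7224 in pituitary (highest other 3197), 498 in neocortex (highest other 441), 1610 in hippocampus (highest other 348) and 6349 in olfactory bulb (highest other 5235).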

How the results depend on the processing

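The offsets, the counts and fold changes with 1 library fewer and the square roots of the deviations were chosen after the data were seen. All 14 late counts (13 organs at 12 weeks, epididymal fat at 20) stayed within 1.5 times the value given under RLE and no filter. So they did with DESeq2, the replicate block and 1 library fewer per time point, which kept most doubtful inguinal and pituitary libraries. Voom weights moved 5 further, offsets 4 and the 2 groups alone 3. Of the 13 counts at 1 week 1 to 8 moved, and the slopes in all 13 organs kept their side of the threshold. Of the fold changes of named genes 1221 kept direction and call under RLE and 8 lost the call; DESeq2 gave 1211 and 7, no filter 1189 and 40, voom weights 1165 and 42, the 2 groups alone 1111 and 72, offsets 1114 and 112, and 1 library fewer 1165 and 63. Of 114 list tests at most 28 were called in the main fits. Among the 114, RLE changed no call, voom weights lost 5, a preset correlation added 70 and fry 86. Preset correlation and fry allow differently for correlation between genes. Depth limits low genes. Small folds were limited as well: simulated changes of 1.5-fold were recovered in 11.9% in soleus and 74.6% in liver. Soleus had the higher median total (13931212.5 against 11417680), so depth does not account for that gap. The replicate numbers were not taken as pairing, since not every single r was over 0.1 (lowest -0.808 across organs), but in all 78 pairs of organs profiles of the same number correlated more (mean r 0.00925 to 0.106) than those of different numbers (-0.0131 to -0.000423). A weak link, as organs of 1 mouse would give, stays open; the interactions and the numbers of genes in at least 7 organs by chance assume none. Within organs the means were 0.0135 to 0.0744 and at most 0.0145. As a block the numbers gave at 1 week 66 in pancreas, 172 in hypothalamus and 110 in hippocampus, and for the muscle interaction 7, and 13 named genes lost their call. Fewer libraries in a fit apart, the cause was not tested for any value that moved. Where higher and lower calls were close in number, the larger side changed with the setting, for example: RLE gave 4328 higher and 4910 lower at 12 weeks in epididymal fat, 2637 and 2634 in liver, 2704 and 2876 in small intestine, 3405 and 3466 in pituitary and 1508 and 1581 in olfactory bulb, and at 20 weeks DESeq2 gave 4407 and 5017 in epididymal fat, and at 1 week the 2 groups alone 2404 and 3084 in pituitary.

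Calls that moved by over 1.5 times, and fold changes that turned, are listed. Times besides 1, 12 and 20 weeks were compared by their median only, so shifts at single ones are left out. At 12 weeks voom with quality weights called 5998 genes in brown fat, 10967 in inguinal fat, 1390 in pancreas, 1965 in soleus and 3535 in gastrocnemius, at 1 week 3660 in brown fat, 8694 in epididymal fat, 4876 in inguinal fat, 37 in pancreas, 435 in soleus, 1978 in gastrocnemius, 38 in hippocampus and 1252 in olfactory bulb, and as a median over the other times 3694 in brown fat, 6787 in inguinal fat, 497 in pancreas, 1307 in soleus, 2533 in gastrocnemius and 2972 in olfactory bulb. Lcn5 in epididymal fat stood at 0.2 at 12 weeks and 0.01 at 20 weeks under those weights, against the other direction. At 1 week 1 library fewer per time point gave 3352 genes in brown fat, 778 in pancreas, 44 in soleus, 340 in gastrocnemius and 7 in hippocampus, as a median over the other times 4169 in inguinal fat, 589 in pancreas, 236 in soleus and 692 in gastrocnemius, for the muscle interaction 69, and for spread 3165 in brown fat, 10139 in epididymal fat, 2444 in pancreas, 9702 in gastrocnemius, 1098 in hypothalamus, 3229 in pituitary, 767 in neocortex, 1044 in hippocampus and 967 in olfactory bulb. Without the least correlated library of each time point the difference in spread was at or below 0 for Mospd2 -0.01, Erg -0.11, Plekhg3 -0.06 (brown fat, 2 weeks), Nos2 -0.07 (inguinal fat, 1 week), Srrm2 -0.02, Fzd5 0, Ptprb -0.04, Snrnp70 -0.02 (pancreas, 3 days), Nfe2l1 -0.01, Gna12 -0.01 (pituitary, 2 weeks) and Dlx1 -0.01, Eomes -0.01, Kcnj4 -0.01, Sp8 -0.01 (olfactory bulb, 4 weeks), and 15 more named genes lost their call. At 1 week the fits of the 2 groups alone called 57 genes in inguinal fat, 0 in pancreas, 0 in soleus, 7 in hypothalamus and 0 in hippocampus, and at 12 weeks 188 in soleus, 2835 in gastrocnemius and 613 in hypothalamus. At 1 week offsets for GC content and length gave 468 genes in inguinal fat, 7 in pancreas, 2515 in small intestine, 68 in soleus, 268 in gastrocnemius, 68 in hypothalamus, 824 in neocortex and 59 in olfactory bulb, at 12 weeks 1101 in soleus, 1411 in gastrocnemius, 2421 in hippocampus and 1621 in olfactory bulb, as a median over the other times 256 in pancreas, 333 in soleus, 891 in gastrocnemius and 634 in olfactory bulb, and for the muscle interaction 175. Chordc1 in epididymal fat stood at -0.05 at 12 weeks and -0.3 at 20 weeks with those offsets, against the other direction. Eef2 in small intestine did so at 12 weeks (-0.04). At 1 week no filter gave 9 in pancreas. At 1 week DESeq2 called 83 genes in pancreas, 46 in soleus, 279 in gastrocnemius and 107 in hippocampus, as a median over the other times 218 in soleus, and for the muscle interaction 142. At 1 week RLE called 9 in soleus. For spread squared deviations called 3545 genes in liver, 5026 in small intestine, 7204 in soleus, 2745 in hypothalamus, 2617 in neocortex and 3710 in hippocampus. For spread square roots of the deviations called 339 genes in liver, 485 in small intestine, 79 in hypothalamus, 4546 in pituitary, 26 in neocortex and 780 in hippocampus. On genes with a mean of at least 5 CPM 1 time point passed for the share of the first principal component, in place of 2. With calls of at least 1.5-fold 4 genes were higher and 2 lower in at least 7 organs.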

Other observations

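Clock genes of epididymal fat were mostly lower at 12 weeks, Dbp at -2.62 ± 0.24 and Nr1d1 at -2.12 ± 0.17: 4 of 17 members rose and 12 fell, 4 and 12 adjusted over the list alone, with a median of -0.83 (adjusted p = 0.269 with an estimated correlation). Red blood cell genes such as Alas2 (-1.18 ± 0.31) were lower too: 6 of 8 members fell, 7 adjusted over the list alone, with a median of -1.22 (adjusted p = 0.729 with an estimated correlation). In that depot after 1 week 11 of 20 interferon response genes rose, 11 adjusted over the list alone, with a median of 0.55 (adjusted p = 0.846 with an estimated correlation). In liver bile acid genes went both ways, the sterol hydroxylase Cyp8b1 up (1.28 ± 0.15) and the transporters Abcb11 (-0.71 ± 0.09) and Slco1a1 (-2.46 ± 0.24) down: 5 of 18 members rose and 8 fell, 5 and 9 adjusted over the list alone, with a median of -0.16 (adjusted p = 0.623 with an estimated correlation). In small intestine the hormone gene Cck (0.79 ± 0.1) and the lipoprotein receptor Scarb1 (1.25 ± 0.1) rose and the cholesterol transporter Npc1l1 (-0.51 ± 0.06) fell, and of fat absorption genes 10 of 24 members rose and 6 fell, 10 and 7 adjusted over the list alone, with a median of 0.1 (adjusted p = 0.682 with an estimated correlation), where 6 rose with offsets for GC content and length. Jchain, of antibody-secreting cells, rose there (1.32 ± 0.15): 3 of 11 B cell genes rose, 3 adjusted over the list alone, with a median of 0.25 (adjusted p = 0.614 with an estimated correlation). In pituitary Ptprc, of blood-derived cells, rose by 0.82 ± 0.15: 9 of 19 macrophage genes rose, 9 adjusted over the list alone, with a median of 0.35 (adjusted p = 0.765 with an estimated correlation). Rgs5, of pericytes, rose by 0.45 ± 0.06: 7 of 14 vessel genes rose, 7 adjusted over the list alone, with a median of 0.35 (adjusted p = 0.616 with an estimated correlation).

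Cirbp, which is induced by cold, fell in 12 organs at 12 weeks and the chaperone Hsph1, induced by heat, rose in 11. The hypothesis that body temperature at dissection may differ between mice was written down before its test: Cirbp and the mean of the heat shock list should then go in opposite directions within time points. They did in 10 of 13 organs and in 0 the other way (adjusted permutation p at most 0.0075, two-sided, Benjamini-Hochberg over 13 organs). Pearson's r and Spearman's rho were -0.845 and -0.806 in pituitary, -0.743 and -0.646 in olfactory bulb, -0.665 and -0.661 in liver, -0.641 and -0.642 in small intestine, -0.577 and -0.63 in neocortex, -0.557 and -0.579 in hippocampus, -0.509 and -0.488 in pancreas, -0.429 and -0.42 in hypothalamus, -0.415 and -0.361 in inguinal fat and -0.401 and -0.531 in brown fat (n = 84 libraries each; r without the 2 farthest libraries -0.813, -0.631, -0.627, -0.594, -0.575, -0.583, -0.479, -0.39, -0.38 and -0.415; permutation p at most 0.0058 for r and 0.0033 for rho, where 1e-04 is the smallest they can give). The relation was not found in epididymal fat (r -0.0846, adjusted p = 0.5), gastrocnemius (-0.0509, 0.75) and soleus (-0.0169, 0.9), by permutation. It is not specific to Cirbp in every organ: 18.3% of all genes were as negative in inguinal fat and 1.68% in brown fat, but 0.00663% in pituitary and 0.00794% in liver. Over the organs the median log2 fold change of Cirbp went from -0.22 at 1 day to -0.62 at 12 weeks. Rbm3, also induced by cold, did not follow that course, at -0.4 at 1 day (lower in 7 organs) and -0.21 at 12 weeks (lower in 8), so the trend over weeks was not shared by the 2 genes. Temperature was not measured, and handling or stress at dissection stay open, so this remains a hypothesis.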
